A study of Mus musculus with 3 samples.

How the data were processed

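Single-cell RNA-seq with the 10x Chromium platform was performed on monocytes and macrophages isolated from skin wounds of male C57BL6/J mice, an inbred laboratory strain, on day 3, day 6 and day 10 after injury. Each of the 3 days is represented by 1 library, and per the labels each library is a pool of 2 mice. The mice of a pool cannot be separated, so each day has 1 sample and there are no replicates.

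The deposited matrices hold counts of unique molecular identifiers (UMIs), which are raw whole numbers per gene and barcode and were not normalised by the authors. Per the labels' protocols, wound tissue was digested enzymatically, cells with a viability of over 70% were loaded, and libraries were sequenced on a HiSeq instrument with paired-end reads. Reads were processed with Cell Ranger 3.0.2 against the mm10 build, per the submitters' processing notes. The gene annotation release used for counting is not given in the sources used here, and neither are the gates of the isolation. The deposited counts cover 31053 gene identifiers in each library, of which 30934 were found by Ensembl identifier in the GENCODE vM21 annotation of GRCm38, the assembly that mm10 names, which supplied the coordinates. Names shared by more than 1 identifier (71 names) were kept apart by identifier. The chemistry counts transcript ends, so splice forms were not distinguished, and near-identical genes can share or lose UMIs.

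Cells with at least 200 detected genes and under 10% of UMIs from mitochondrially encoded genes were kept. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were ranked within each library with scanpy 1.11.5. All kept cells were then clustered together on 30 principal components with 15 neighbours, shared-neighbour weights and the Leiden algorithm at a resolution of 0.8 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0). No batch integration was applied, because library and day are the same. Doublets were scored per library with Scrublet through scanpy and were kept in the main values.

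Clusters were named from 16 marker lists that were written before the data were examined, as were the gene lists, the rule for named genes and most of the alternative settings. The rule that applied the markers was set after seeing the data. A cluster was called monocyte/macrophage when at least 5 of the 29 monocyte and macrophage markers had at least 50 CPM (counts scaled to the total of the sum) and a level at or above that of all other cells. Another class needed at least 3 of its own markers at 50 CPM, in at least 25% of the cells and at 4 times their level elsewhere, and a larger share of its list. A cluster whose 10 leading genes held more markers of another class than of its own stayed unnamed. Monocytes and macrophages were treated as 1 class, because they form a continuum and the isolation aimed at both.

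UMIs were summed over the cells of the class in each library and expressed as CPM. Ratios of CPM were formed between day 10 and day 3, between day 6 and day 3 and between day 10 and day 6. No test was run and no p-value is given, since each day has 1 library. CPM values carry exact Poisson 95% intervals, ratios carry exact conditional binomial 95% intervals, and shares of cells carry exact binomial (Clopper-Pearson) 95% intervals. All intervals cover counting error only and say nothing about the spread between mice. A gene entered a comparison with at least 20 UMIs over both libraries, and a library with under 3 UMIs of a gene was set to 3. An interval of a list median is the central 95% of 500 Poisson redraws of the counts.

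Genes were named by a rule of size. The 12 genes with the largest and the 12 with the smallest ratio were taken for day 10 against day 3, and 6 in each direction for the other pairs of days, among genes with at least 100 CPM in at least 1 of the libraries compared. Mitochondrially encoded genes, ribosomal protein genes, uncharacterised gene models and markers of classes other than monocyte and macrophage were left out. Members of 30 fixed gene lists were taken as well, for each list the 2 members with the largest ratio in each direction, along with 18 genes fixed for the shares of cells. Not all of these are printed, so a printed member need not have the largest ratio of its list. Of a list, members at least 1.5-fold higher or lower are counted, and its median log2 ratio is given with its percentile among 10000 random lists of the same size matched on mean CPM in 20 bins, as a description of these libraries. Values inside clusters are ratios between days within each cluster with at least 50 cells in both libraries. A cluster's own 10 leading genes were left out of its list medians and of its counts of named genes. Such values can therefore cover fewer genes than those of the class. Named genes with under 3 UMIs in both libraries were not counted inside a cluster either.

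For shares of cells with a UMI, each cell was thinned at random to 2000 UMIs and shallower cells were left out, because the libraries differ in depth. At that depth 1 UMI equals 500 CPM in a cell. Cells with at least 2 UMIs over 24 G2/M genes were counted as cells with G2/M transcripts. The alternative without G2/M cells left out cells with at least 2 such UMIs before thinning. Deep cells pass that limit more easily, and the day 6 class sum fell from 4450083 to 3142814 UMIs. Shares in dendritic-cell-like cells are given beside them as a level that includes free RNA in the droplets.

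The functions for ratios, intervals, lists and thinning were tested on simulated data drawn from the real gene means and library totals, with 199 or 200 measured genes changed 2- or 4-fold per pair of days. For day 10 against day 3, with 11729 genes, 96% of the intervals held the true ratio. The values were 95.6% of 11414 genes for day 6 against day 3 and 95.6% of 11583 genes for day 10 against day 6. Among 300 unchanged lists per pair, 8.33%, 5.67% and 5.67% lay outside the central 95% of the random lists for these pairs, so that a percentile near the edge of that range is weak evidence. For a profile simulated at different depths, 71.5% and 96.6% of gene and cell pairs had a UMI before thinning, and 48% and 47.9% after it.

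Alternatives changed 1 choice at a time, except that the settings for the filter on cells change or drop the gene minimum and the mitochondrial limit together, so that their parts cannot be separated. The alternatives covered no cell filter, at least 1000 genes with under 5% mitochondrial UMIs, Leiden resolutions of 0.4 and 1.2, clustering without genes that differed 2-fold between libraries, and removal of called doublets. Under each of these, and under the mitochondrial limit of 20%, cells were clustered and named anew. The cells counted in the class therefore changed along with the stated choice, and ranges over the alternatives include this. Scaling was changed to TMM factors from edgeR 4.0.16 (R 4.3.3), median-of-ratios factors, means of per-cell CPM, and totals without ribosomal protein and mitochondrially encoded genes. Other settings took all kept cells in place of the class, or the class without cells that had at least 2 G2/M UMIs. Minimums of 5 and 100 UMIs, sums thinned to the smallest library, and other thinning depths and G2/M thresholds were used as well. Further alternatives were chosen after seeing the data. They were a mitochondrial limit of 20%, the class without hemoglobin-rich cells, unnamed clusters counted in the class, all kept cells for the G2/M share, and clusters with at least 20 cells. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and anndata 0.12.19, and plots were drawn with matplotlib 3.10.9.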

Results

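To follow the heterogeneity of monocytes and macrophages through skin wound healing in mice, cells isolated from wounds on day 3, day 6 and day 10 after injury were profiled by droplet single-cell RNA-seq, which counts mRNA molecules per cell as UMIs. Each day was represented by 1 library made from 2 pooled male mice, so no difference between days could be set against the spread between animals, and every comparison describes these 3 libraries. The day 3 library held 1472 barcodes and 11199361 UMIs, the day 6 library 1196 barcodes and 9273960 UMIs, and the day 10 library 2209 barcodes and 13972817 UMIs. After the filter on detected genes and mitochondrial UMIs, 900, 598 and 1362 cells were kept, which was 61.1% (95% binomial interval 58.6 to 63.6%), 50% (47.1 to 52.9%) and 61.7% (59.6 to 63.7%) of the barcodes. Most barcodes that were left out had 10% or more of their UMIs from mitochondrially encoded genes (572, 595 and 844 barcodes). Kept cells had medians of 10629, 11778.5 and 8285 UMIs.

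Clustering of the 2860 kept cells gave 16 clusters, and 11 of them, with 2332 cells, were named monocyte/macrophage-like from the fixed markers. The class made up 84.6% (82.0 to 86.9%) of the kept cells at day 3, 73.1% (69.3 to 76.6%) at day 6 and 83.3% (81.2 to 85.2%) at day 10, in cells that had been isolated as monocytes and macrophages, so the isolation sets these shares along with the wound. The filter on cells and the clustering moved them, and the lowest shares over the alternatives were 61.5% at day 3 and 65.6% at day 10 with a mitochondrial limit of 20% and 56.1% at day 6 with no filter. Dendritic-cell-like clusters, led by Cd209a or by Ccr7 and Ccl22, held 133, 135 and 191 cells, or 14.8%, 22.6% and 14%. An endothelial-like cluster held 0, 2 and 7 cells, where 0 of 900 cells allows a share of up to 0.333% taken as 3 cells of the total (exact 95% upper bound 0.409%). A pair of clusters stayed unnamed under a rule set after seeing the data and held 0.667%, 4.01% and 2.20% of the cells of the 3 days. Scrublet called 10, 5 and 5 cells as doublets, few enough that undetected doublets are to be expected, and these cells were kept.

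The class sums held 761, 437 and 1134 cells with 7540643, 4450083 and 8970757 UMIs. The clusters that held most of the class differed between days, except that days 6 and 10 shared clusters 2 and 5. Clusters 3, 6 and 8 held most of it at day 3, clusters 2, 5, 9 and 11 at day 6, and clusters 4, 2, 5 and 7 at day 10. Cluster 4, with 276 of its 294 cells from day 10, and cluster 7, with 139 of 149, were nearly made of the day 10 library, and a cluster mostly of 1 library may be that library and not a cell type. Markers of other cell types in the class sums stayed low and differed between days. Fibroblast markers summed to 5.44, 32.1 and 45 CPM at days 3, 6 and 10, keratinocyte markers to 3.71, 5.39 and 7.25, endothelial markers to 14.6, 20.4 and 24.9, and pericyte markers to 10.3, 6.97 and 6.91 CPM. Neutrophil markers stood at 265, 439 and 233 CPM and dendritic cell markers at 64.7, 34.2 and 34.9 CPM. Markers of B cells (63.3, 38.2 and 34.8 CPM) and of natural killer or innate lymphoid cells (9.55, 5.39 and 3.34) were highest at day 3, while those of Langerhans cells (4.77, 7.42 and 4.01) and plasmacytoid dendritic cells (1.99, 5.39 and 2.34) were highest at day 6. T cell, mast cell and melanocyte markers stayed at or under 2.25 CPM each day. Erythroid and platelet markers stood apart at 73.3, 2882 and 41.8 CPM, because 4 day 6 cells carried large amounts of hemoglobin mRNA.

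The first comparison set day 10 against day 3. The class at day 10 carried less of the transcripts induced by interferon and of those typical of blood monocytes, and the medians of macrophage and hypoxia lists were higher. All 18 measured genes of the type I interferon response were at least 1.5-fold lower at day 10, with a median of 6.81-fold (log2 −2.77, counting interval −2.92 to −2.63). All 12 classical monocyte genes were lower as well, with a median of 4.03-fold (log2 −2.01, −2.17 to −1.92). Mature macrophage genes were higher by a median of 2.93-fold, resident dermal macrophage genes by 4.11-fold (2.17-fold over all kept cells), growth factors by 2.5-fold (1.61-fold with no cell filter, and with list sums of 2142 against 1989 CPM) and hypoxia response genes by 2.18-fold. The medians of these 6 lists lay outside those of all 10000 matched random lists.

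Among genes with at least 100 CPM on 1 of the days and outside the markers of other cell types, to which the naming by size was limited, the metallothionein Mt2, which binds zinc and copper, had the largest ratio, with 510 CPM at day 10 and 7.82 CPM at day 3 (ENSMUSG00000031762, mm10 chromosome 8, 94172664 to 94173568). The ratio was 65.2-fold (counting interval 50.5 to 85.8) and 38.4- to 164-fold over the alternative settings, and such a range, or the most distant value, is given where a setting moved a ratio by over 1.5-fold. Its neighbour Mt1 was 8.76-fold higher (8.38 to 9.15). Sox4, a transcription factor, was 29.9-fold higher (20.3 to 46.0, alternatives 23.9 to 46.8), and Cav1, the coat protein of caveolae, 17.3-fold (13.5 to 22.4). The collagen-degrading cathepsin gene Ctsk stood at 158 against 13 CPM, or 12.1-fold higher (9.89 to 15.1, alternatives 5.62 to 28.2). The macrophage elastase gene Mmp12 (ENSMUSG00000049723, chromosome 9, 7344381 to 7369499) stood at 1042 against 111 CPM, or 9.36-fold higher (8.72 to 10.1). Its ratio was the least settled of the named genes, at 5.52- to 118-fold over the alternatives. The metalloproteinase inhibitor gene Timp2 was 7.13-fold higher (6.44 to 7.92) and the serpin gene Serpinb6a 10.5-fold (8.80 to 12.6, alternatives 9.29 to 17.8). Egln3, an oxygen-dependent prolyl hydroxylase that acts on hypoxia-inducible factor (ENSMUSG00000035105, chromosome 12, 54178981 to 54203860), was 10.3-fold higher (8.51 to 12.6). The chemokine gene Ccl8 was 10.1-fold higher (8.29 to 12.4, alternatives 4.32 to 11.5), the costimulatory receptor gene Tnfrsf9 9.24-fold (7.82 to 11), and Nrp2, a co-receptor for semaphorins and vascular growth factors, 6.96-fold (5.91 to 8.24).

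Of the 12 genes with the smallest ratios under the same limit, 7 belong to the fixed interferon list. Slfn4, a Schlafen family gene of myeloid cells (ENSMUSG00000000204, chromosome 11, 83175186 to 83190216), had 15 CPM at day 10 and 394 CPM at day 3 and was 26.2-fold lower (22.0 to 31.4). Isg15, a ubiquitin-like modifier (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818), stood at 79.4 against 914 CPM and was 11.5-fold lower (10.7 to 12.5). The oligoadenylate synthetase family genes Oas3, Oasl1 and Oasl2 were 10.9-, 10.1- and 8.14-fold lower. Irf7, a transcription factor that amplifies interferon production, was 8.94-fold lower (8.10 to 9.89), and the nucleic acid sensor gene Zbp1 8.78-fold (7.87 to 9.83). Rtp4 was 9.18-fold lower, Phf11b 9.23-fold (alternatives 4.76 to 10.5) and Ifi205 8.68-fold. Chil3 and Ms4a4c belong to the classical monocyte list. Chil3, which encodes the chitinase-like protein Ym1 (ENSMUSG00000040809, chromosome 3, 106147554 to 106167564), stood at 224 against 1955 CPM, 8.74-fold lower (8.34 to 9.17), and Ms4a4c was 13.1-fold lower (12.2 to 14.1, alternatives 7.21 to 15.2). Day 6 lay between day 3 and day 10 for these 7 interferon genes, as the plot of CPM by day shows.

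**Figure D1:**
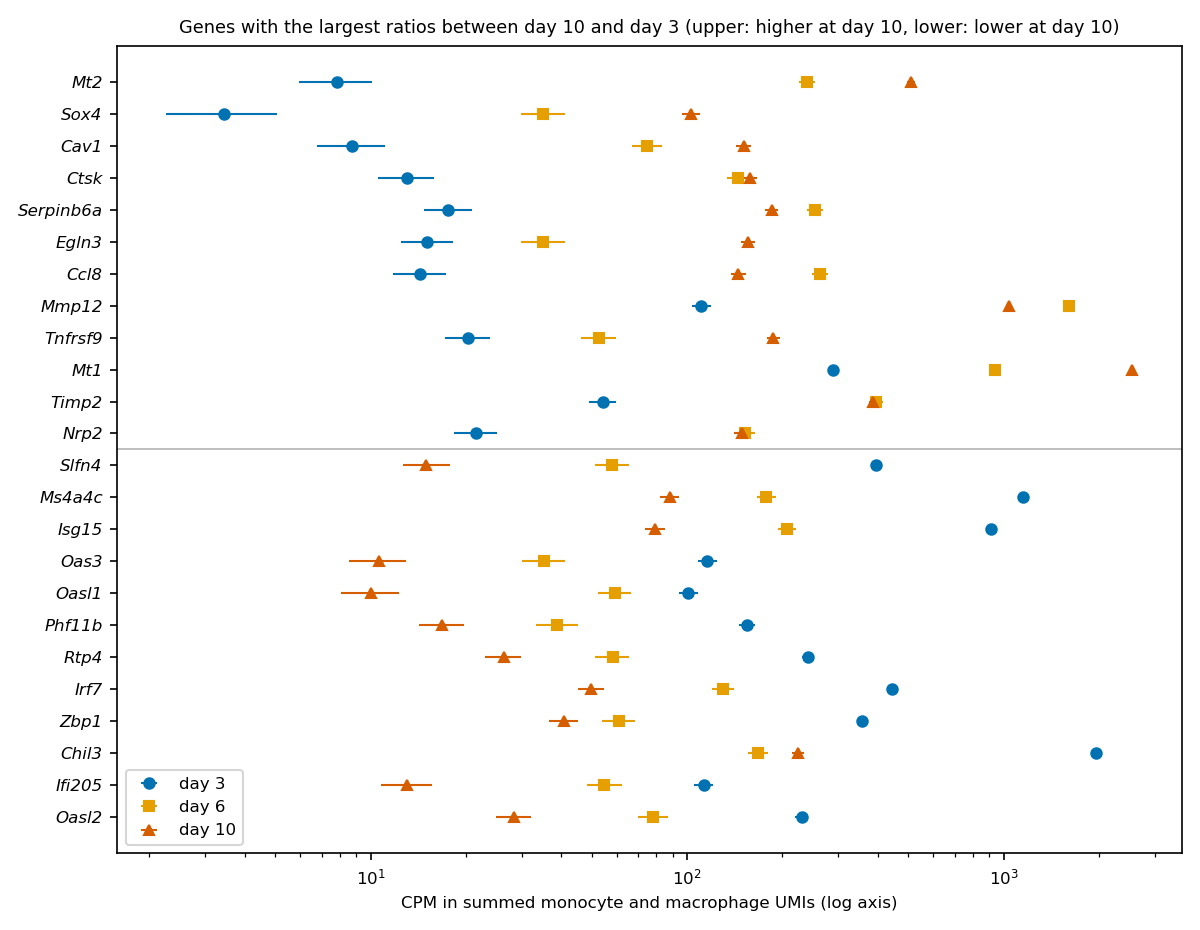
CPM in the summed monocyte and macrophage UMIs of each library (log axis) for the 12 genes with the largest and the 12 with the smallest ratio between day 10 and day 3, 1 library per day, with exact Poisson 95% intervals that cover counting error only. Mt2 stood at 7.82, 239 and 510 CPM at days 3, 6 and 10, and Isg15 at 914, 207 and 79.4 CPM.

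Macrophage identity genes were higher in 11 of the 15 measured members of the mature macrophage list and lower in 1. Tmem119 was 10.5-fold higher (7.88 to 14.3), Cd63 6.63-fold (6.2 to 7.10) and the complement gene C1qa 4.56-fold (4.37 to 4.75), while the Fc receptor gene Fcgr1 was 4.33-fold lower (4.09 to 4.59). The resident dermal macrophage list had 11 of 15 members higher and none lower, with Gas6, a bridging ligand in the uptake of dead cells, 11.7-fold higher (8.38 to 16.7). Efferocytosis genes were higher in 11 of 15 members (median log2 0.95), and lysosome genes in 11 of 19 (0.64), with none lower in either list, and Atp6v0d2 was 6.79-fold higher (alternatives 5.84 to 19.6). Of the 19 lipid handling genes, 12 were higher and 1 was lower (median log2 0.95). Gpnmb was 5.22-fold higher (4.37 to 6.27, alternatives 4.57 to 8.88), and the cholesterol transfer gene Npc2 was 1.64-fold lower (1.60 to 1.68). MHC class II genes lay within 1.5-fold in 7 of 8 members, with H2-Ab1 1.39-fold higher. H2-DMa was 1.53-fold lower, but its log2 ratio was 0.08 over all kept cells, and that of H2-DMb1 was 0.12 with no cell filter. MHC class I genes were lower in 7 of 12 members and higher in none (median log2 −0.71), led by H2-T23 at 3.08-fold (2.88 to 3.29).

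Genes induced by low oxygen were higher in 11 of the 15 measured members of the hypoxia response list and lower in none. The median log2 ratio was 1.13 (0.96 to 1.29). Beside Egln3, Vegfa, which encodes the main angiogenic growth factor, stood at 608 against 363 CPM, 1.68-fold higher (1.60 to 1.76). Hif1a itself was 1.24-fold higher (1.19 to 1.29) and Bhlhe40 1.01-fold. Glycolysis genes were higher in 5 of 16 members and lower in none, with a median log2 ratio of 0.39 at percentile 99.8, led by hexokinase 2 (Hk2, 1.74-fold) and the glucose transporter gene Slc2a1 (1.73-fold). Oxidative phosphorylation genes lay within 1.5-fold in 19 of 21 members (median log2 −0.12), with cytochrome c (Cycs) 1.91-fold lower. Antioxidant response genes were higher in 7 of 14 and lower in none (0.62), and iron and heme genes were higher in 9 of 14 and lower in 2 (0.94). In the latter list the hemoglobin scavenger receptor gene Cd163 was 5.82-fold higher (4.15 to 8.37), haptoglobin (Hp) 3.33-fold lower (3.16 to 3.52) and lipocalin 2 (Lcn2) 16.7-fold lower (10.8 to 27.1). In dendritic-cell-like cells of the same libraries, the hypoxia and glycolysis lists had medians of −0.45 and −0.39.

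Inflammatory transcripts were mostly lower at day 10, with a large exception. Of 13 measured inflammatory cytokine and enzyme genes, 9 were lower and 3 higher (median log2 −0.75, −0.88 to −0.67). Il6 was 8.55-fold lower (6.31 to 11.8, alternatives 7.05 to 13.5), Cxcl10 4.96-fold (4.56 to 5.39) and Il1b 1.83-fold, from 4366 to 2392 CPM. The inducible nitric oxide synthase gene Nos2 was 54.7-fold higher (27.6 to 127, alternatives 26.9 to 98.6), with 58.1 CPM against 1.06 CPM, and the prostaglandin synthase gene Ptges 11.2-fold (7.60 to 17.0, alternatives 3.25 to 11.4). Tnf differed by 1.12-fold. Chemokines were lower in 8 of 14 members and higher in 4 (median log2 −1.13, list sums 16420 against 22149 CPM), where Ccl24 was 7.86-fold lower (alternatives 4.60 to 9.49) and Ccl12 7.33-fold (alternatives 4.67 to 8.19), and Cxcl16 was 4.64-fold higher (4.26 to 5.05). Alternative activation genes divided, with 4 higher, 3 lower and 9 within 1.5-fold of 16. The arginase gene Arg1 was 3.55-fold higher (3.47 to 3.64) with 3939 CPM at day 10, and the mannose receptor gene Mrc1 was 1.36-fold higher. Cd209a was 4.09-fold lower, but 1.01-fold with no cell filter. Retnla was 2.65-fold higher, and up to 22.9-fold over the alternatives, from 404 and 128 UMIs, the latter in 6 cells. A cluster led by Retnla stayed unnamed and outside the class. NF-kB feedback genes were lower in 2 of 13 (Nfkb1 1.94-fold) and higher in none. Chemoattractant and adhesion receptors were lower in 6 of 16 and higher in 3, and the fractalkine receptor gene Cx3cr1 was 2.93-fold higher (2.57 to 3.36). Pattern recognition receptors were lower in 6 of 16 and higher in none, with Nod2 3.27-fold lower (2.49 to 4.35).

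Growth factor genes were higher in 10 of 16 members and lower in 3. Vegfb was 11.8-fold higher (5.77 to 27.9) and Pdgfc 10.8-fold (5.04 to 27.6, alternatives 8.84 to 24.8), both from about 1 CPM at day 3. Insulin-like growth factor 1 (Igf1) was 4.67-fold higher (3.5 to 6.32, alternatives 3.23 to 7.86), Areg was 2.77-fold lower (2.29 to 3.37, alternatives 2.36 to 9.90), and Tgfb1 differed by 1.09-fold. In the matrix and protease list, 9 of 21 genes were higher and 5 lower. Beside Ctsk, the gelatinase gene Mmp9 was 9.87-fold higher (6.66 to 15.2, alternatives 5.16 to 21.1), and versican (Vcan) and thrombospondin 1 (Thbs1), which monocytes carry in quantity, were 3.86-fold (3.64 to 4.09) and 2.24-fold (2.20 to 2.29) lower. Osteopontin (Spp1), from the lipid handling list, was 2.31-fold higher, but its log2 ratio was −0.25 with no cell filter.

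S phase genes were higher in 11 of 16 members and lower in 1 (median log2 0.75, percentile 96.0), among them Mcm3 at 2.77-fold (1.99 to 3.93). G2/M genes had few UMIs, with a median log2 ratio of 0.32 (−0.03 to 0.82) that was 1.91 at a minimum of 100 UMIs. Kif23 was 2.05-fold lower (1.11 to 3.89), but its log2 ratio was 0.88 with no cell filter, 0.38 over all kept cells and 0.48 with unnamed clusters counted. Unfolded protein response genes were lower in 7 of 14 and higher in 1 (median log2 −0.71), where Creld2 was 4.61-fold lower (3.84 to 5.55) and Sdf2l1 4-fold. Genes that dissociation can induce were lower in 9 of 22 and higher in 4, and these included the near-identical heat shock genes Hspa1a (5.23-fold lower) and Hspa1b (5.43-fold lower, alternatives 3.58 to 6.07), between which UMIs can be lost or misassigned, while Egr1 was 3.92-fold higher (3.71 to 4.14). Cholesterol synthesis genes stayed within 1.5-fold in 10 of 15 (median log2 −0.18), and the median was 0.05 over all kept cells. Circadian clock genes were higher in 5 of 11 and lower in 1 (0.56, but with list sums of 123.4 against 133.1 CPM), with Nr1d2 4.70-fold higher (2.97 to 7.77) and Per1 2.5-fold lower (2.14 to 2.94). Ribosomal protein and mitochondrially encoded genes had medians of 0.17 and −0.08.

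Under CPM, the median over all genes was 0.16 for day 10 against day 3 and 0.23 for day 6 against day 3, and TMM factors shifted all log2 ratios of these pairs by −0.16 and −0.23 (median-of-ratios factors by −0.124 and −0.205), so small list medians are to be read against these values. The clusters that differed between days also carried these genes, since Mt2, Mt1, Nos2, Tnfrsf9, Sox4 and Egln3 were among the leading genes of cluster 4 and Slfn4, Isg15, Irf7 and Ly6c2 of clusters 3 or 6, and no cluster of the class held 50 cells of both days. With at least 20 cells, a limit chosen after seeing the data, the interferon median was −2.31 in cluster 5 (198 and 22 cells), −0.78 in cluster 10 (64 and 45), −0.11 in cluster 8 (21 and 116) and 0.84 in cluster 3 (31 and 315). The value of cluster 3 leaves out Ifit3, Irf7, Ifit2 and Isg15, which lead that cluster, so it covers fewer genes than the class median. The hypoxia median in these clusters was 0.48, −0.51, −0.06 and −0.90. Of the named higher genes counted in clusters 5, 10, 8 and 3, 11 of 12, 3 of 5, 5 of 7 and 10 of 12 kept their direction. Of the named lower genes, 12 of 12, 12 of 12, 7 of 11 and 5 of 9 did.

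The second comparison set day 6 against day 3, the earlier step of the time course. Monocyte transcripts were lower and macrophage, lipid handling, lysosome and efferocytosis transcripts higher at day 6. All 12 classical monocyte genes were lower, with a median of 7.55-fold (log2 −2.92, −2.97 to −2.80). Mature macrophage genes were higher in 13 of 15 members and lower in 1 (median 3.52-fold), resident dermal macrophage genes were higher in 13 of 15 (3.79-fold), efferocytosis genes in 11 of 14 (2.95-fold), lipid handling genes in 15 of 19 (2.87-fold) and lysosome genes in 13 of 19 (2.51-fold), with no member of the last 4 lists lower. Each of these medians lay outside those of all 10000 random lists.

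Mt2 was again the gene with the largest ratio under this limit, which leaves out hemoglobin genes, at 239 against 7.82 CPM or 30.6-fold (23.5 to 40.4, alternatives 16.5 to 61.9). Gpnmb, a transmembrane glycoprotein of lipid-laden macrophages (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929), stood at 513 against 19.0 CPM, 27.0-fold higher (22.8 to 32.2, alternatives 18.5 to 47.6). The fatty acid binding protein gene Fabp4 was 21.0-fold higher (15.5 to 29, alternatives 7.03 to 26.4). Genes of resident macrophages were next, with Cd163 20.8-fold higher (15 to 29.6, but 4.01 to 25.9 over the alternatives), Gas6 20-fold (14.3 to 28.6) and Ccl8 18.4-fold (15.1 to 22.6, alternatives 7.88 to 21.6). Among the lower genes, Dmkn, a secreted protein known from epidermis, stood at 7.19 against 191 CPM, 26.6-fold lower (18.8 to 39.1, alternatives 22.9 to 40.9). Chil3 was 11.7-fold lower (10.8 to 12.6), Ifitm6 10.8-fold (9.23 to 12.7, alternatives 3.65 to 12.7) and Plac8 8.93-fold (8.41 to 9.48, alternatives 5.75 to 10.5). Ly6c2, the surface marker of inflammatory monocytes (ENSMUSG00000022584, chromosome 15, 75108158 to 75111970), stood at 80.4 against 707 CPM and was 8.79-fold lower (7.90 to 9.81).

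Interferon response genes were lower in 14 of 18 members and higher in none at day 6 (median log2 −1.24, −1.32 to −1.13), with Zbp1 5.87-fold and Isg15 4.41-fold lower. Growth factors were higher in 11 of 16 and lower in 1 (median 3.74-fold, but 1.70-fold at a minimum of 100 UMIs, with list sums of 2924 against 1989 CPM). Igf1 stood at 110 against 7.43 CPM, 14.9-fold higher (11.3 to 20, alternatives 12 to 25.3), and oncostatin M (Osm) was 2.66-fold lower (2.48 to 2.85). Matrix and protease genes were higher in 13 of 21 and lower in 4 (median log2 0.73), led by Mmp12 at 1608 against 111 CPM, 14.4-fold higher (13.4 to 15.5, alternatives 10.0 to 134), while Vcan was 4.70-fold lower. Inflammatory genes were lower in 7 of 13 and higher in 4 (−0.92). Il18 was 4.85-fold lower (3.85 to 6.19), Tnf was 2.26-fold higher (but 1.16-fold with no cell filter), and Ptges was 13.6-fold higher, although its log2 ratio was −0.07 with no cell filter. Chemokines were lower in 7 of 14 and higher in 4 (−0.59), with Ccl2 4.01-fold lower (3.82 to 4.20) and Cxcl16 5.03-fold higher (alternatives 3.32 to 6.00). Alternative activation genes were higher in 9 of 16 and lower in 3 (median log2 0.72, percentile 99.8), among them Il10 at 4.11-fold (3.36 to 5.05). Retnla was 2.16-fold lower, a direction that turned under 7 settings (log2 2.97 with no cell filter). The unnamed cluster led by Retnla lies outside the class, and with unnamed clusters counted the log2 ratio was 2.63. MHC class II genes were higher in 4 of 8 and lower in none, with H2-Eb1 2.12-fold higher (2.04 to 2.20).

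Hypoxia response genes were higher in 8 of 14 members and lower in none (median log2 0.68, 0.62 to 0.74), with Ndrg1 2.30-fold higher (2.05 to 2.59), while glycolysis genes had a median of −0.14, with Slc16a3 1.85-fold lower. Cholesterol synthesis genes were lower in 8 of 14 and higher in 1 (−0.81, −1.02 to −0.58). Iron and heme genes were higher in 7 of 14 and lower in 2 (0.73), antioxidant genes higher in 8 of 14 and lower in 2 (0.79), and S phase genes higher in 11 of 16 and lower in 1 (0.99). Oxidative phosphorylation genes had a median of −0.24, and for Cox5a, which was 1.14-fold higher, the log2 ratio was −0.05 under TMM and −0.02 under median-of-ratios factors. The other lists had medians of −0.12 (NF-kB feedback), −0.25 (MHC class I), 0.36 (G2/M, 0.08 to 2.37 over the alternatives), −0.29 (dissociation), −0.52 (unfolded protein response), −0.33 (receptors), −0.32 (pattern recognition), 0.30 (clock), −0.10 (ribosomal proteins) and 0.01 (mitochondrially encoded genes, −0.23 under TMM). The day 6 sum held the 4 hemoglobin-rich cells and the highest neutrophil marker level, and Dmkn and Chil3 lead cluster 8, mostly of day 3, as Mmp12, Gpnmb and Ctsk lead cluster 11. No cluster of the class held 50 cells of both days, and with at least 20 cells the monocyte median was −1.41, −1.68 and −0.70 in clusters 3, 5 and 6 (22, 60 and 21 day 6 cells), while the lipid handling median was 0.94, 0.62 and 0.20. In these clusters 6 of 6, 1 of 3 and 3 of 3 of the named higher genes counted kept their direction, and 5 of 5, 5 of 5 and 5 of 6 of the lower ones.

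The third comparison set day 10 against day 6, the later step. The median levels of the hypoxia and glycolysis lists were higher at day 10, and those of the interferon, lipid handling and resident macrophage lists were lower. Hypoxia response genes were higher in 8 of 15 members and lower in 1 (median log2 0.68, 0.47 to 0.74), and glycolysis genes were higher in 6 of 16 and lower in none (0.49, 0.45 to 0.53), each above all 10000 random lists. Interferon response genes were lower in 17 of 18 (median 2.61-fold), lipid handling genes in 10 of 19 (1.59-fold) and resident dermal macrophage genes in 9 of 15 with 1 higher (1.71-fold), each below all random lists. The list sums differed less, with 24149 against 27384 CPM for lipid handling and 5993 against 6146 CPM for resident macrophage genes.

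Among genes with at least 100 CPM on 1 of the days and outside the markers of other cell types, Egln3 had the largest ratio, with 156 against 35.1 CPM or 4.44-fold (3.76 to 5.28, alternatives 3.69 to 7.18). The next genes under this limit were Tnfrsf9 (3.56-fold, 3.11 to 4.10, alternatives 3.49 to 10.2), the acute phase gene Saa3 (3.06-fold, 2.78 to 3.37, alternatives 2.57 to 4.68), Fam162a, a gene induced by hypoxia-inducible factor (3.01-fold, 2.68 to 3.39), Sox4 (2.94-fold, alternatives 2.62 to 4.84) and Ifitm6 (2.78-fold, alternatives 1.43 to 3.39). Lipoprotein lipase (Lpl, ENSMUSG00000015568, chromosome 8, 68880491 to 68907448) had the smallest ratio under this limit, with 182 against 1318 CPM or 7.22-fold lower (6.84 to 7.64, alternatives 4.44 to 8.69). The antiviral gene Rsad2 was 5.72-fold lower (5 to 6.55, alternatives 3.36 to 5.83), Gpnmb 5.18-fold (4.79 to 5.60) and Fabp4 5.17-fold (4.42 to 6.06, alternatives 2.24 to 5.94). The heat shock genes Hsph1 and Hspa1b were 5.14-fold (4.37 to 6.06) and 4.89-fold (4.67 to 5.12) lower.

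In the fixed lists, which carry no such limit, some ratios were larger. In the hypoxia list the vasoactive peptide gene Adm was 8.79-fold higher (4.81 to 17.9, alternatives 8.63 to 22.9), and in the glycolysis list Slc2a1 was 2.21-fold (2.01 to 2.43) and Hk2 1.89-fold higher. Nos2 was 5.38-fold (4 to 7.40, alternatives 4.50 to 9.73) and Arg1 2.14-fold (2.09 to 2.19) higher. Il6 was 3.82-fold lower (but 1.18-fold without cells that had at least 2 G2/M UMIs), Tnf 2.53-fold (but 1.52-fold without them) and Il10 3.67-fold lower (3.06 to 4.42). Growth factors were lower in 8 of 16 and higher in none (median log2 −0.56), with Igf1 3.18-fold lower. Lysosome genes were lower in 8 of 19 (−0.38), efferocytosis genes in 6 of 14 (−0.22), with Cd36 2.92-fold lower (2.74 to 3.10), and MHC class II genes in 3 of 8 (−0.54), with none higher in these 3 lists. Cd163 was 3.58-fold lower, but with at least 1000 genes and under 5% mitochondrial UMIs its log2 ratio was 0.06. Cholesterol synthesis genes were higher in 6 of 15 and lower in none (0.50), with Sqle 2.25-fold higher (1.44 to 3.67), and classical monocyte genes were higher in 4 of 12 and lower in 1 (0.45), with Cd177 5.90-fold higher (2.99 to 13.2). Alternative activation genes were lower in 7 of 16 and higher in 2 (−0.39), a median that was 0.02 under the stricter cell filter, while their summed level was higher at day 10, at 7419 against 5176 CPM. The G2/M median was −0.22 (−0.95 to 0.50 over the alternatives), and medians of the other lists lay between −0.41 (chemokines) and 0.29 (ribosomal proteins).

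This pair of days shared clusters 2 (225 and 168 cells) and 5 (198 and 60 cells) at 50 cells or more. Inside them the interferon median was −1.39 and −0.37, the hypoxia median 0.29 and 1.01 and the glycolysis median 0.24 and 0.72, while the lipid handling median was −0.33 and 0.06. All 6 named genes that were higher at day 10 were higher in both clusters. Of the named lower genes, 5 of 5 were lower in cluster 2, where Gpnmb was left out as a leading gene, and 5 of 6 in cluster 5. These genes were chosen by their ratio in the class sum, which holds these cells. With at least 20 cells, clusters 3, 9, 11 and 12 were shared as well. Of the named higher genes counted there, 2 of 5, 2 of 6, 4 of 6 and 2 of 3 kept their direction. Of the lower ones, 5 of 6, 5 of 6, 4 of 4 and 5 of 6 did, with Lpl and Gpnmb left out in cluster 11, which they lead. The hypoxia median in these 4 clusters was −0.845, −0.004, 0.683 and 0.064, and the interferon median 0.474, −1.245, −1.630 and −0.524.

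**Figure D2:**
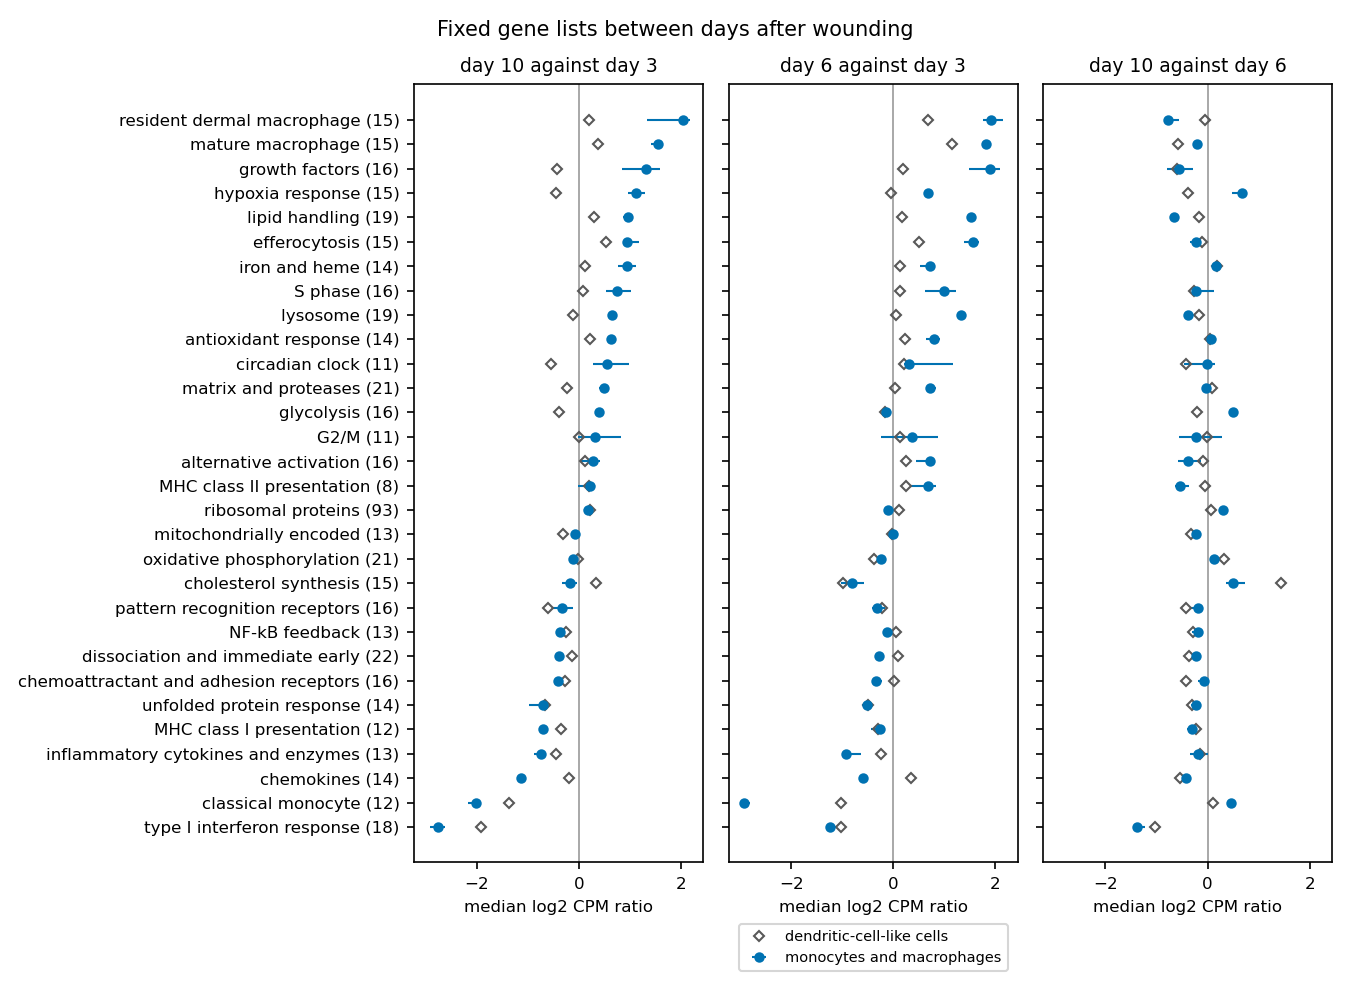
Median log2 CPM ratio of each of the 30 fixed gene lists in the monocyte and macrophage sums (filled circles, with counting intervals of 95%) and in dendritic-cell-like cells of the same libraries (open diamonds), for each pair of days, 1 library per day, with the number of members measured at day 10 against day 3 in parentheses. The interferon list had the lowest median at day 10 against day 3, −2.77 in monocytes and macrophages and −1.92 in dendritic-cell-like cells, and the hypoxia list stood at 1.13 and −0.45.

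To ask whether these levels came with more or fewer cells carrying each transcript, the share of cells with a UMI was taken after thinning to 2000 UMIs, which left out 21, 45 and 86 cells of the class. Median depth before thinning was 9968, 9050 and 7548.5 UMIs in the class and 15963, 17725 and 13570 in dendritic-cell-like cells, the comparison class for free RNA. Ly6c2 was found in 44.9% (41.2 to 48.5%) of the class at day 3, 6.63% (4.38 to 9.57%) at day 6 and 6.39% (4.99 to 8.05%) at day 10, with 12.8%, 1.5% and 4.26% of dendritic-cell-like cells. Before thinning the shares were 66.9%, 10.5% and 10.1%. Chil3 was found in 69.3% (65.9 to 72.6%), 11.5% and 10.0% of cells and in at most 1.5% of dendritic-cell-like cells (78.8%, 22.0% and 14.6% unthinned). Ccr2, the receptor for the chemokine Ccl2, was found in 69.9%, 27.3% and 33.8% (89.1%, 41.9% and 44.6% unthinned), but 54.9%, 53.4% and 64.9% of dendritic-cell-like cells also carried it. C1qa was found in 17.2% (14.5 to 20.1%), 62.0% (57.0 to 66.8%) and 57.1% (54.0 to 60.1%), with 1.5%, 4.51% and 4.26% of dendritic-cell-like cells (22.5%, 67.7% and 64.6% unthinned). Arg1 was found in 34.2% (30.8 to 37.7%), 58.2% (53.1 to 63.1%) and 74.5% (71.8 to 77.1%), with 2.26%, 1.5% and 1.60% (43.1%, 71.9% and 80.5% unthinned). Vegfa followed the same order with 33.9%, 43.6% and 54.3%, beside 4.51%, 2.26% and 3.19% of dendritic-cell-like cells (49.7%, 61.1% and 71.0% unthinned), and Spp1 another with 35.0%, 49.7% and 41.0%, beside 2.26%, 1.5% and 6.38% (48.4%, 63.4% and 53.4% unthinned).

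Igf1 was found in 0.946% (0.381 to 1.94%), 14.3% (11 to 18.1%) and 4.48% (3.31 to 5.92%) of thinned cells (1.97%, 26.8% and 9.96% unthinned), with at most 0.752% of dendritic-cell-like cells. Nos2 was found in 0.135%, 0.765% and 6.77% (5.33 to 8.47%), with at most 0.532% of dendritic-cell-like cells (0.394%, 5.26% and 13% unthinned). Il10 was found in 2.03%, 5.61% and 2% (6.44%, 10.8% and 4.41% unthinned), beside 0% (exact upper bound 2.74%), 0.752% and 0% (1.94%) of dendritic-cell-like cells. Retnla was found in 0.270%, 1.02% and 1.34% beside 0%, 0.752% and 1.6% of dendritic-cell-like cells, so its share in the class does not stand above that level (0.788%, 3.43% and 3.17% unthinned, another order of days 6 and 10). Unnamed cluster 13, with 9992 CPM of Retnla against 48.8 CPM in all other cells, lies outside the class, so its cells are missing from these shares. Il1b was found in 78.1%, 36.7% and 51.0% (88.8%, 47.8% and 57.9% unthinned), close to the shares of dendritic-cell-like cells (75.9%, 40.6% and 45.7%), which express it. Tnf stood at 29.9%, 37.8% and 28.8%, beside 7.52%, 14.3% and 13.3% of dendritic-cell-like cells (58.1%, 54.7% and 51.7% unthinned), where the order of the shares changed with thinning. Mrc1 stood at 27.7%, 36.2% and 35.8% beside 18.0%, 25.6% and 20.2% of dendritic-cell-like cells (50.6%, 58.8% and 58.1% unthinned). Adgre1 stood at 25.4%, 29.6% and 21.5% beside 3.01%, 8.27% and 4.79% (60.8%, 58.4% and 46.6% unthinned, another order). Tgfb1 stood at 39.5%, 32.1% and 35.7% beside 29.3%, 31.6% and 29.8% of dendritic-cell-like cells (81.9%, 67.5% and 69.4% unthinned). H2-Ab1 stood at 20.8%, 32.1% and 31.1% (32.7%, 46.9% and 48.9% unthinned, another order of days 6 and 10), while 96.2%, 100% and 100% of dendritic-cell-like cells had it. Cx3cr1, at 5.14%, 11.5% and 13.4%, lay at or below the level of dendritic-cell-like cells (6.77%, 12% and 16.0%), so these shares do not set the classes apart.

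**Figure D3:**
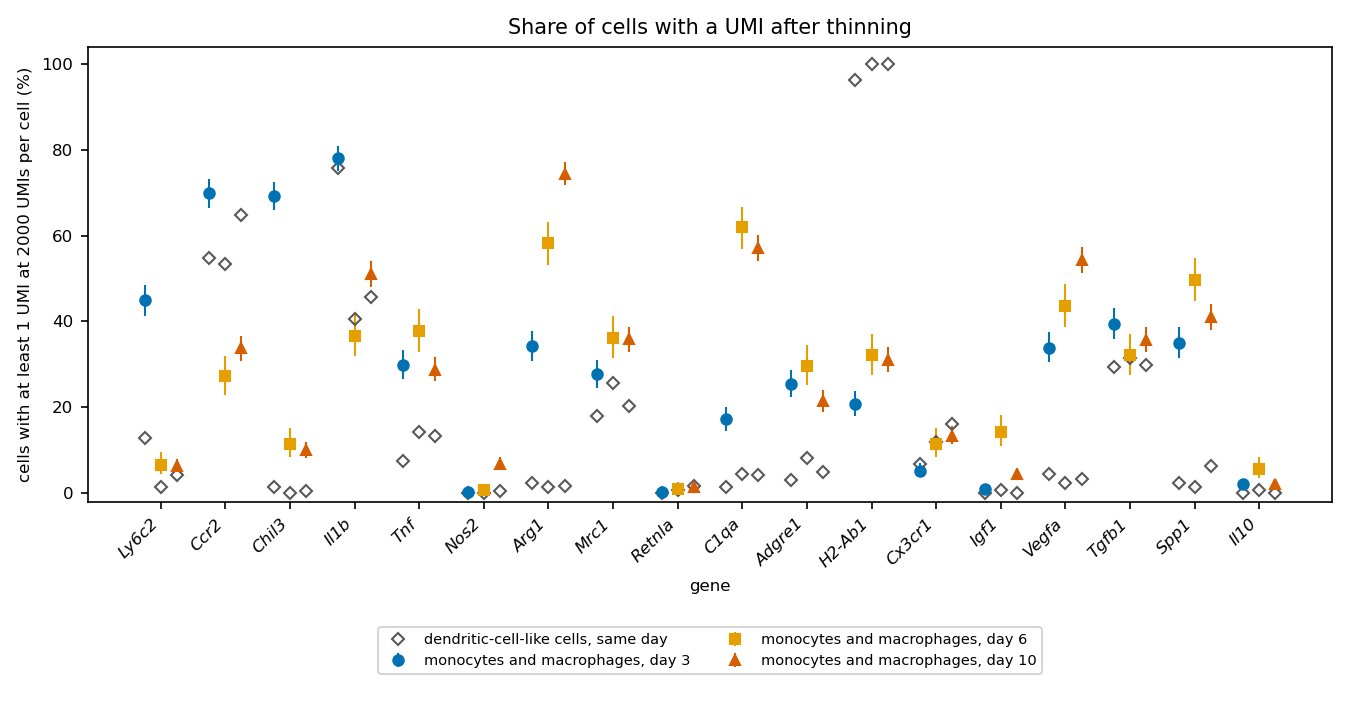
Share of monocyte and macrophage cells with at least 1 UMI of each of 18 genes after thinning each cell to 2000 UMIs (filled symbols, exact binomial 95% intervals, 1 library per day) and the share of dendritic-cell-like cells of the same day (open diamonds, a level that includes free RNA). Chil3 stood at 69.3%, 11.5% and 10.0% at days 3, 6 and 10, and Arg1 at 34.2%, 58.2% and 74.5%.

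Proliferation was read from cells with at least 2 UMIs over the G2/M genes after thinning. They made up 0.541% (0.147 to 1.38%) of the class at day 3, 3.32% (1.78 to 5.60%) at day 6 and 2.48% (1.63 to 3.61%) at day 10. In dendritic-cell-like cells the shares were 3.01%, 2.26% and 2.66%. Whether those cells were cycling themselves was not tested, so they do not give a level without proliferation. Without thinning the shares were 8.54%, 19.0% and 12.8% in the class and 32.3%, 40% and 35.6% in the deeper dendritic-cell-like cells. A cluster led by G2/M genes such as Mki67 and Top2a stayed unnamed and outside the class, so its cells are missing from the class shares.

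To see whether transcripts used to label opposite macrophage states occurred in the same cells, the share of thinned cells with both transcripts was set against the product of the single shares. Il1b and Mrc1 were found together in 21.9% of cells at day 3, 1.01 times the product, and in 6.89% and 13.7% at days 6 and 10, 0.518 and 0.752 times the product. Tnf with Mrc1 gave 1.09, 0.560 and 0.713 times the product. Il1b with Arg1 (1.06, 1.16 and 1.04) stayed near the product on all 3 days. So did Arg1 with Mrc1 (1.03, 0.944 and 1.05), which are both in the alternative activation list and do not label opposite states. Without thinning the Il1b and Mrc1 ratios were 0.991, 0.871 and 0.885, and those of Tnf with Mrc1 1.06, 0.889 and 0.931. At 1000 UMIs the latter were 0.824, 0.546 and 0.785. For both pairs the distance from 1 depends on the depth.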

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

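Of the tests in this part, those of the hypoxia list in dendritic-cell-like cells, of interferon genes in dendritic-cell-like cells, of the number of libraries and of the 4 cells richest in hemoglobin were chosen only after the result was seen.

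In several gene lists the dendritic-cell-like cells differed from the monocytes and macrophages of the same libraries in the direction of the ratio between days, and the difference between the classes was not tested. For day 10 against day 3 the median log2 ratio in dendritic-cell-like cells and in monocytes and macrophages was −0.386 and 0.387 for glycolysis, −0.454 and 1.126 for the hypoxia response, 0.333 and −0.182 for cholesterol synthesis, −0.429 and 1.321 for growth factors, and −0.232 and 0.501 for matrix and proteases. For day 6 against day 3 the chemokine medians were 0.359 and −0.594. For day 10 against day 6 the hypoxia medians were −0.391 and 0.678.

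The higher hypoxia response at day 10 than at day 3 was weighed against 3 technical explanations. For handling of the whole day 10 sample, the list was read in dendritic-cell-like cells, where its median was −0.454 (−0.562 to −0.255). The list was flagged because it went the other way in these cells, so this value cannot decide on handling. That handling would raise the list in every class is also an assumption. Damaged cells and depth were set against a bound of 0.563, and the median stayed above it. It was 1.060 (0.893 to 1.227) with at least 1000 genes and under 5% mitochondrial UMIs. With the class sums thinned to the smallest total it was 1.172 (1.005 to 1.339). These ranges carry over the width of the main counting interval and were not redrawn under each setting. Random thinning of sums leaves ratios of CPM nearly as they were, so the thinned value cannot decide on depth. What also stays open is how far the higher hypoxia response reflects which clusters each library holds. Inside clusters with at least 20 cells, the median was 0.481 in cluster 5 but −0.898, −0.056 and −0.509 in clusters 3, 8 and 10. Low oxygen in the wound was not tested as an explanation.

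The interferon response list was lower at day 10 than at day 3 in dendritic-cell-like cells too, with a median of −1.921 beside −2.767. Free RNA from day 3 monocytes would bring all their transcripts at a similar low share, but the interferon genes stood at a median of 52.7% of the monocyte and macrophage level in dendritic-cell-like cells at day 3 (range over genes 18 to 114%), while Chil3 stood at 0.548% (0.343 to 0.83%). A difference between the libraries other than the day cannot be told apart from the day, because there is 1 library per day. The stage of wound healing remains an untested explanation.

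Hemoglobin transcripts stood at 2844 CPM in the day 6 class sum, against 1.19 CPM at day 3 and 0.78 CPM at day 10. Free RNA from lysed red cells would be spread over many droplets, but 4 cells of cluster 2 held 99.9% of these UMIs, with 4170, 3746, 2430 and 2295 hemoglobin UMIs each. Red cells caught in the same droplets as macrophages cannot be told apart from engulfed red cells, since these 4 cells had a median of 4891 other UMIs, above the 5th percentile of their cluster (984.75 UMIs), which either would give. No biological explanation was tested.

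Some groups of cells and barcodes were not studied as a subject of their own. They were the 36 cells of unnamed cluster 13, the 24 cells of unnamed cluster 14, the 459 dendritic-cell-like cells, which serve as the class set beside the monocytes and macrophages, the 9 endothelial-like cells, the 4 cells with over 1000 hemoglobin UMIs, which are part of the day 6 class sum, and the 2017 barcodes left out by the filter on cells.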

How the results depend on the processing

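Of the settings in this part, the mitochondrial limit of 20%, the class without hemoglobin-rich cells, unnamed clusters counted in the class, all kept cells for the G2/M share and clusters with at least 20 cells were chosen after seeing the data, as was the choice of 1 leading list per pair of days. Of 1618 list medians recomputed under alternatives, 1172 stayed within their counting interval, 439 left it and 7 changed direction in the sense given below, and of 6128 values of named genes the numbers were 4735, 1354 and 39. No detection share, G2/M share or class share could change direction, and 118 of 132, 14 of 15 and 14 of 24 of these left their interval. The detection shares were recomputed only at other thinning depths, which move them by construction. The number of genes past a 2-fold difference was dropped as a result, because counts of changed genes are not given with 1 library per day. Depth limits the comparisons with day 6 most, since its class sum holds 4450083 UMIs against 7540643 and 8970757.

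The leading medians kept their direction under each alternative run on the class sums or on all kept cells. Inside clusters with at least 20 cells, as given above, some did not. The interferon median was above 0 in cluster 3 at day 10 against day 3, and the hypoxia median was below 0 in clusters 3 and 9 at day 10 against day 6. For the interferon list at day 10 against day 3, −2.77 became −2.459 with no filter on cells, −2.585 with under 20% mitochondrial UMIs, −2.537 over all kept cells and −2.927 under TMM. For the monocyte list at day 6 against day 3, −2.92 became −2.991 with at least 1000 genes and under 5% mitochondrial UMIs, −2.977 with under 20%, −3.036 at a Leiden resolution of 1.2, −3.149 under TMM, −3.122 under median-of-ratios factors, −3.019 with means of per-cell CPM, −2.524 over all kept cells and −2.710 without G2/M cells. For the hypoxia list at day 10 against day 6, 0.678 became 0.849 with no filter, 0.751 under TMM and 0.760 under median of ratios. The scaling factors shift all ratios of a pair alike; for the other settings the cause was not tested.

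A change of direction is given for genes whose counting interval in the main setting excluded a ratio of 1 and for lists outside the central 95% of the random lists; other values also crossed 0, such as Aurkb at day 10 against day 3 (1.132 with no filter on cells). The values are log2 ratios. Under the settings of this paragraph cells were clustered and named anew, so the clusters counted in the class changed too. With no filter, a cluster led by Mmp12, Spp1 and Ptges (33, 148 and 177 cells at days 3, 6 and 10) stayed unnamed and outside the class. A cluster with Retnla, Mki67 and Top2a among its leading genes (8, 44 and 42 cells) was named monocyte/macrophage. How much of each value came from such changes was not tested. With no filter on cells they were, at day 10 against day 3, −0.248 for Spp1, 0.881 for Kif23 and 0.120 for H2-DMb1; at day 6 against day 3, −0.069 for Ptges, 0.924 for Tyms, 1.228 for Kif23, −0.008 for Nlrp3, −0.115 for Dnajb9, 2.966 for Retnla, 0.383 for H2-DMa, −0.069 for Vegfa and −0.159 for Pgam1. At day 10 against day 6 they were 1.230 for Lcn2 and 0.127 for the dissociation list. With at least 1000 genes and under 5% mitochondrial UMIs, Ednrb was −0.583 and Retnla 1.850 at day 6 against day 3, and Lcn2 was 1.072, Cd163 0.061, the alternative activation list 0.020 and the dissociation list 0.026 at day 10 against day 6. With under 20% mitochondrial UMIs, Retnla was 2.577 (day 6 against day 3) and Lcn2 0.990 (day 10 against day 6). Retnla was 1.521 at a Leiden resolution of 1.2.

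Clustering without 2-fold different genes gave 0.001 for the alternative activation list, 0.009 for the dissociation list and −0.008 for Apoe, all at day 10 against day 6, and a minimum of 100 UMIs gave 0.093 for alternative activation. Over all kept cells, the cholesterol synthesis list was 0.053, Kif23 0.382 and H2-DMa 0.083 at day 10 against day 3, Tyms 0.530, Kif23 0.317, Retnla 2.426 and H2-DMa 0.632 at day 6 against day 3, and Spp1 0.008 at day 10 against day 6. Without G2/M cells, Retnla was 2.010 at day 6 against day 3, and Ckap2l 0.503 and Spp1 0.080 at day 10 against day 6. With unnamed clusters counted, Kif23 was 0.482 at day 10 against day 3, and Tyms 0.813, Kif23 0.638, Retnla 2.630 and H2-DMa 0.194 at day 6 against day 3. Per-cell means gave −0.158 for Ednrb, and TMM and median of ratios gave −0.047 and −0.020 for Cox5a, at day 6 against day 3. The Cox5a values follow from the shift of all log2 ratios of this pair, −0.232 under TMM and −0.205 under median of ratios. Counting unnamed clusters adds only the cells of cluster 13, led by Retnla, and of cluster 14, led by G2/M genes. For the remaining settings of this paragraph the cause was not tested.

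The class share depends by construction on the share of cells left in unnamed clusters, which was 0.667%, 4.01% and 2.2% in the main setting and 27%, 23.9% and 23.2% with under 20% mitochondrial UMIs. With that limit the class share was 61.50% at day 3, 58.30% at day 6 and 65.57% at day 10. With no filter it was 56.10% at day 6 and 66.91% at day 10, with at least 1000 genes and under 5% mitochondrial UMIs 78.62%, 56.82% and 73.15%, at a resolution of 1.2 73.44% at day 3, and without 2-fold different genes 73.44%, 58.70% and 75.99%. Counting unnamed clusters gave 77.09% at day 6 and 85.46% at day 10. How much of each move came from other steps was not tested. The G2/M share followed the depth and the threshold by construction. It was 0.00%, 0.47% and 0.72% at 1000 UMIs, 8.54%, 18.99% and 12.79% with no thinning, 7.16%, 14.03% and 13.17% at 1 UMI or more and 0.00%, 1.53% and 0.67% at 3 or more. Over all kept cells it was 1.48% at day 3 and 3.62% at day 10.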

Other observations

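The dendritic-cell-like cells, measured in the same libraries, carried more cholesterol synthesis transcripts at day 10 than at day 6, with a median log2 ratio of 1.436 over 13 measured genes, of which 11 were higher. At day 6 against day 3 the median of this list was −0.979. Their interferon response genes were lower at day 10 than at day 3 in all 18 measured members (median −1.921), and their unfolded protein response genes had a median of −0.667. Mature macrophage genes in these cells had a median of 1.155 at day 6 against day 3. Their list sum at day 6 was 1203 CPM, against 20562 CPM in monocytes and macrophages. Free RNA or doublets with macrophages were not tested as sources of these transcripts.

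Heat shock transcripts were chosen for this part after their values were seen. In monocytes and macrophages Hspa1a stood at 2339, 1617 and 447 CPM at days 3, 6 and 10, and in dendritic-cell-like cells at 2900, 5229 and 1456 CPM. Hspa1b stood at 1530, 1377 and 282 CPM and at 1792, 3678 and 1028 CPM, and Hsph1 at 51.2, 120 and 23.3 CPM and at 72.1, 256 and 43 CPM. Hspa8 stood at 3373, 2353 and 1626 CPM and at 3831, 2746 and 1478 CPM. The other measured heat shock genes went both ways in monocytes and macrophages. Hspd1 stood at 61, 93.9 and 72.1 CPM, Hspe1 at 164, 207 and 180 CPM and Hspb1 at 1.99, 2.7 and 7.36 CPM, and Dnajb1 stood at 60.1, 77.1 and 49.5 CPM and Hsp90aa1 at 460, 794 and 418 CPM.

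Unnamed cluster 13, with 3, 16 and 17 cells from days 3, 6 and 10, carried 9992 CPM of Retnla against 48.8 CPM in all other cells, and 918 against 29.5 CPM of Ear2. Fcrls (890 against 41.8 CPM) and Batf3 (291 against 29.3 CPM) were also among its leading genes. Unnamed cluster 14, with 3, 8 and 13 cells, carried Mki67 at 633 against 9.28 CPM and Top2a at 517 against 3.15 CPM. These genes define the clusters and are given as values only.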
